A study of Mus musculus with 6 samples.

How the data were processed

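Bulk RNA sequencing of 6 livers was analysed, 3 from Sirt5+/+ and 3 from Sirt5-/- male mice of the C57BL/6 strain, taken 20 days after hydrodynamic injection of the YAP5SA and transposase plasmids. One deposited table held all values. The tools were HISAT2 2.1.0, RSEM 1.3.1 and DESeq2 1.24.0 per the submitters' processing notes, which do not give the role of each tool, its options or the genome build. The expected counts (estimated reads per gene, not scaled between libraries and in part not whole numbers) were used as deposited by the authors, with RSEM among the tools of the submitters' processing notes. The deposited TPM values, made by the authors before deposit, were only checked for being in that unit. The deposited log2 fold changes and p-values, raw and adjusted, are those of the authors' comparison, with DESeq2 among the tools of the submitters' processing notes, and were used only for the comparison of called genes. The gene IDs and names of all 55536 entries are those of GENCODE M21, so coordinates are given on GRCm38 (mm10). Of these genes 30117 had no count in any library.

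Library totals ran from 19307808 to 24330797 counts, and 16723 to 20954 genes were detected. A floor of 3 counts in a library equals 0.0827 to 0.393 CPM (counts scaled to the same total in each library), so lower levels cannot be told from none. Mitochondrially encoded genes took 6.58 to 46.4% of counts, and 4 nuclear copies of these genes a further 2.08 to 14.3%.

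Expected counts were rounded to whole numbers, genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15) and scaled with TMM factors, which ran from 0.396 to 1.68. The comparison was Sirt5-/- minus Sirt5+/+ with genotype as the only term, tested two-sided with the edgeR 4.0.16 quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over 14799 genes, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.373. CPM in the text use TMM factors, with the SD between 3 libraries.

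The gene lists were 45 sets from textbook knowledge of liver metabolism, cell types and the subjects of the series title, 828 entries of which 744 were measured. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and beside it with an estimated correlation and with fry, each adjusted over the 45 lists. For each list the members past the threshold were counted over all genes and adjusted over the list alone. GO and KEGG terms of the deposited annotation with 10 to 500 tested genes were tested with one-sided Fisher's exact tests, higher and lower genes apart, against tested genes with an annotation of that kind (12687 and 5834).

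The genes named were chosen by a rule: Sirt5; the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 1 CPM, no overlap between genotypes and an established symbol; and the members with the smallest p of each list, up to 4 for the lists closest to the series title and up to 2 for the others. This rule named 128 genes besides Sirt5, and 48 more were named after their values were seen; 4 of these 176 genes are not reported here but are counted with the rest. List members given below only as too low to be tested are not counted among the genes named. The design, lists, rule and first set of alternatives were fixed before the data were examined. For genes with 1 to 3 counts over a group, ratios carry exact Clopper-Pearson 95% intervals, which cover counting error only, and a group with no count was set to a floor of 3 counts over the group.

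Sequence shared between genes was measured as the percent of the 31-base words of a gene's transcripts that occur in other genes of GENCODE M21, for all genes named. Lists were also compared relative to the mean log2 CPM of hepatocyte markers in each library, with an exact two-sided permutation test of the 20 assignments of 3 libraries against 3, a measure chosen after seeing the data.

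The alternatives fixed first were the replicate number as a block, DESeq2 size factors, library totals, upper-quartile factors, no filter, a stricter filter (1 CPM in 3 libraries and a mean of 50 counts), DESeq2 1.42.0, limma-voom, other thresholds, leaving out each library in turn and the authors' deposited calls. Those chosen after seeing the data were leaving out the library richest in mitochondrial reads of each genotype, removing mitochondrial genes and their nuclear copies, the mitochondrial share as a covariate, an offset for GC content, sample quality weights in limma-voom, and the block for terms. The 4 added lists of cell subsets in the closing section were chosen after the first lists had been seen and before the values of their own genes were.

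The steps were tested on simulated data with the means and library sizes of these samples. Of 50 genes each changed 1.5, 2, 4 and 8-fold, edgeR recovered 0, 2, 64 and 86%, and it called 4 of 14579 unchanged genes. DESeq2 recovered 0, 24, 88 and 94%, and limma-voom 0, 0, 60 and 82%, and they called 37 and 3 of the unchanged genes. Camera called the list made to change (adjusted p = 4.67e-16) and 0 of 44 others, fry called it (adjusted p = 0.00486) and 1 of 44 others, and Fisher's exact test called 0 of 201 unchanged terms. The simulated genes were drawn independently, so false calls from correlation between genes could not appear. Fisher's exact test was given the genes made to change, not those called by edgeR. The analysis used R 4.3.3 with the data.table package (1.17.8), and Python 3.11.15 with matplotlib 3.10.9 for sequence words and figures.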

Results

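RNA was sequenced from 6 male mouse livers of the C57BL/6 strain, 3 from animals without the gene for the mitochondrial deacylase SIRT5 (Sirt5-/-) and 3 from animals with it (Sirt5+/+). All animals had received, at 4 weeks of age, a hydrodynamic injection, in which a large volume pushed into the circulation carries plasmid DNA into hepatocytes. The plasmids were 50 µg of a construct for YAP5SA, an active form of the transcriptional co-activator YAP, and 10 µg of a transposase construct, and livers were taken 20 days later. The series title places the comparison in the question of how loss of SIRT5 bears on liver tumour formation, bile acids and the immune environment. Library totals were 21461691, 23410091 and 19307808 estimated read counts in Sirt5+/+ replicates 1 to 3, and 20025180, 24330797 and 21648299 in Sirt5-/- replicates 1 to 3. The labels do not say that the livers are separate animals, so p-values measure the spread between these samples only.

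Sirt5 itself was low in every Sirt5-/- library. The gene (ENSMUSG00000054021, chromosome 13, 43365496 to 43395203, plus strand, GRCm38) had 352, 441 and 96 counts in the Sirt5+/+ libraries and 14, 45 and 18 counts in the Sirt5-/- libraries. Mean levels of Sirt5 were 15.01 ± 2.16 CPM (SD, n = 3) against 0.851 ± 0.373 CPM (SD, n = 3). On the log2 scale Sirt5 fell by 4.13 ± 0.38 (SE; edgeR quasi-likelihood test, adjusted p = 0.00146), so each library matched its genotype label. Of the other sirtuins, Sirt3, the main mitochondrial deacetylase, fell by 2.18 ± 0.37 (SE; adjusted p = 0.00368, edgeR) and Sirt7 fell by 0.83 ± 0.25 (SE; adjusted p = 0.0313, edgeR). The 6 sirtuins besides Sirt5 did not pass as a list (2 fell and 4 did not pass, and the same counts held adjusted over the list alone; camera adjusted p = 0.326, and 0.401 with an estimated correlation; fry adjusted p = 0.0209, lower), and their median of -0.46 became 0.15 when libraries were scaled by their totals. Sirt7 missed the threshold without Sirt5+/+ replicate 1 or without Sirt5-/- replicate 2 or 3 (adjusted p from 0.0624 to 0.160), and both Sirt3 (0.0678) and Sirt7 (0.878) missed it with library totals.

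Livers without Sirt5 had lower levels of hepatocyte genes, including the enzymes and transporters of bile acid metabolism, and higher levels of YAP target, cell cycle, immune and matrix genes. Of 14799 genes tested, 5100 differed at an adjusted p under 0.05 (edgeR), 2575 higher and 2525 lower in Sirt5-/-. At least 2-fold changes made up 2375 of the higher and 2123 of the lower genes. The genotypes did not overlap in 49.8% of tested genes, against 10% by chance for 3 against 3. The authors' deposited table held 6058 genes at an adjusted p under 0.05, and 5087 of these were also called here in the same direction. The first principal component, 62.0% of the variance, separated the genotypes, and the second, 24.4%, set Sirt5+/+ replicate 3 apart.

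Mitochondrially encoded genes took 7.20, 6.58 and 46.4% of counts in Sirt5+/+ replicates 1 to 3 and 40.8, 21.5 and 17.5% in Sirt5-/- replicates 1 to 3. Without the richest library of each genotype, an alternative chosen after seeing the data, 7439 genes differed, 3904 of them higher. The count was 2677 without Sirt5-/- replicate 2 and 2531 without Sirt5-/- replicate 3, and without Sirt5+/+ replicate 3 it was 7647, 3991 of them higher. Scaling by library totals moved the median log2 fold change of all genes from -0.08 to 0.60 and left 2763 changed genes, 2438 higher and 325 lower (88.2% higher, against 50.5%). Upper-quartile factors moved that median to 0.11 and gave 2963 higher and 1953 lower genes. Directions below are relative to the typical gene, and with library totals 56 of the 176 named genes besides Sirt5 kept their direction but missed the threshold.

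Among 45 gene lists fixed before the data were examined, 37 passed camera's test with a preset correlation of 0.01, 17 higher and 20 lower in Sirt5-/-. None passed when the correlation between genes was estimated from these libraries (camera, adjusted p from 0.177 to 0.949, with 11 lists at an unadjusted p under 0.05), and fry's directional test called 39. Lists with an estimated correlation below the preset lost their call too, such as T and NK cell markers (-0.026) and neutrophil markers (-0.155). Correlation between genes thus does not by itself account for all the lost calls. The adjusted p-values with an estimated correlation given below should therefore not be read as the effect of correlation alone. Camera with the preset correlation also called up to 33 lists when the libraries were split into groups that mixed the genotypes, so its calls describe these 6 livers. Of the 3 Sirt5+/+ livers, replicate 3 had the mean list level nearest to the Sirt5-/- mean in 28 of the 37 lists, and of the Sirt5-/- livers replicate 1 lay nearest to the Sirt5+/+ mean in 25. These are the livers richest in mitochondrial reads of each genotype. The plot of list members shows the whole range.

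**Figure D1:**
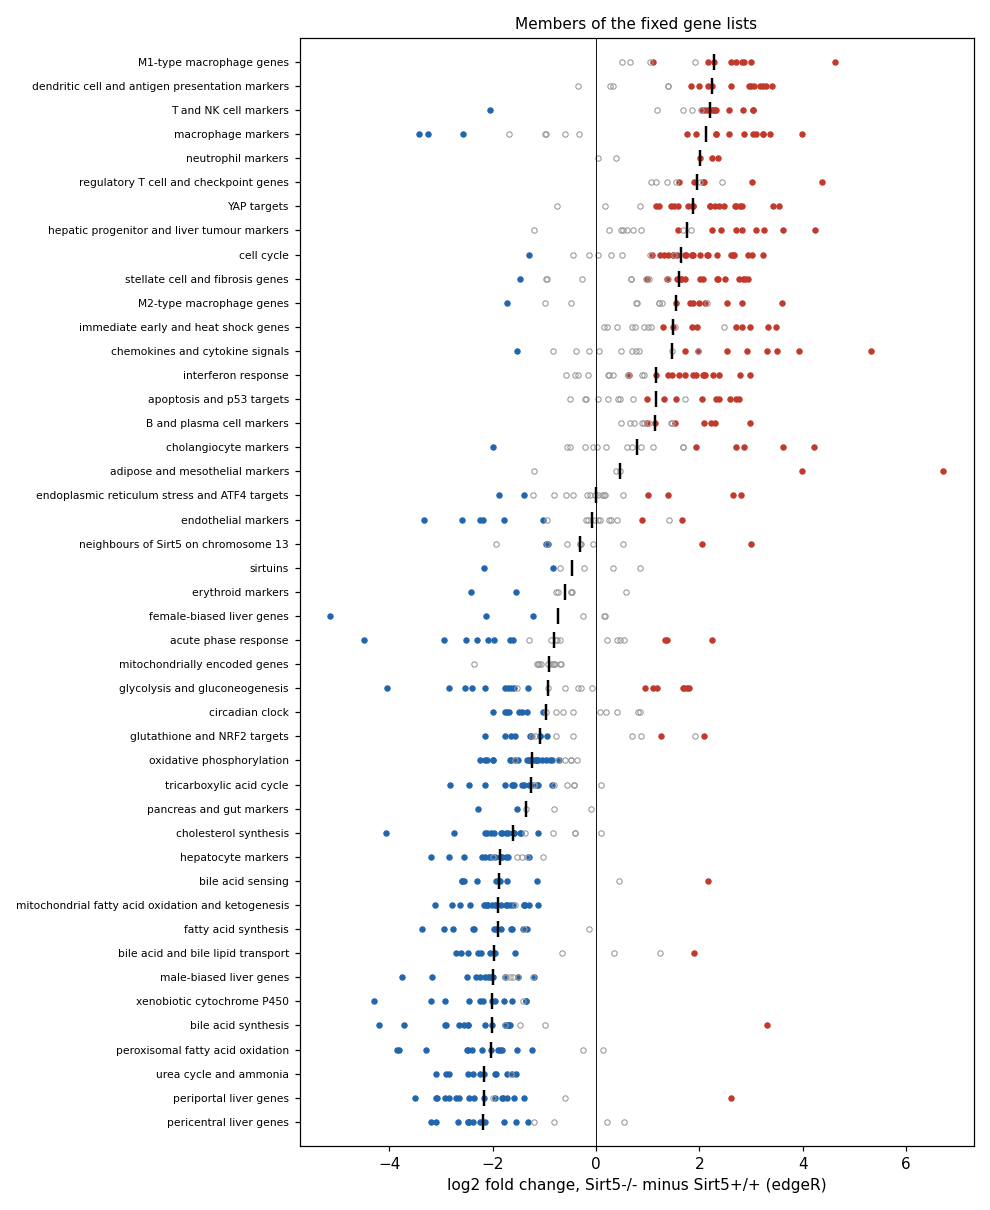
Fitted log2 fold changes (x axis, Sirt5-/- minus Sirt5+/+) of the measured members of the 45 gene lists (rows, ordered by their median, drawn as a black bar). Filled points passed an adjusted p under 0.05 in edgeR (red higher, blue lower) and open grey points did not; Lep, with no count in Sirt5+/+, is drawn at its fitted value. Medians ran from -2.19 for pericentral liver genes to 2.29 for M1-type macrophage genes, and those of endothelial, sirtuin, mitochondrially encoded and Sirt5-neighbour lists changed sign with library totals.

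Bile acid genes were lower on all 3 fronts listed, synthesis, transport and sensing. Of 19 measured synthesis genes, 15 fell and 1 rose (18 and 1 adjusted over the list alone), with a median log2 change of -2.01 (camera adjusted p = 6.72e-07, but adjusted p = 0.177 with an estimated correlation). The mean centred log2 level of the list was 1.22, 1.18 and 0.41 in Sirt5+/+ replicates 1 to 3. Slc27a2, an acyl-CoA synthetase, fell from 612 ± 86.7 to 110 ± 22.8 CPM (SD, n = 3). Cyp8b1, the sterol 12-alpha-hydroxylase needed for cholic acid, fell by 2.92 ± 0.43 on the log2 scale (SE; adjusted p = 0.00247, edgeR), and Baat, which conjugates bile acids to amino acids, fell by 1.76 ± 0.25 (SE). Amacr, a peroxisomal racemase of the side-chain pathway, fell by 2.01 ± 0.28 (SE). Cyp7a1, the first enzyme of the classic pathway, fell by 1.71 ± 0.46 (SE; adjusted p = 0.0218), and the cholesterol 25-hydroxylase Ch25h was the gene that rose, by 3.30 ± 0.81 (SE; adjusted p = 0.0152). Both were named after their values were seen, and both lost their calls without Sirt5+/+ replicate 2 or Sirt5-/- replicate 3, Cyp7a1 also without Sirt5-/- replicate 2 and Ch25h without Sirt5+/+ replicate 1 (adjusted p up to 0.0873 and 0.0731). The log2 change of Ch25h was 4.07 without Sirt5+/+ replicate 3 and 2.63 without Sirt5-/- replicate 3. With library totals Amacr, Baat and Cyp7a1 missed the threshold (log2 changes of -1.45, -1.18 and -1.39, adjusted p = 0.140, 0.251 and 0.160).

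Among 14 measured transport genes, 10 fell and 1 rose (10 and 2 adjusted over the list alone), with a median of -1.98 (camera adjusted p = 0.00102, but adjusted p = 0.177 with an estimated correlation). Abcb11, the bile salt export pump, fell from 301 ± 26.8 to 61.5 ± 13.7 CPM (SD, n = 3). The phospholipid flippase gene Abcb4 fell by 2.62 ± 0.39 and the sterol transporter gene Abcg5 fell by 1.98 ± 0.26 on the log2 scale (SE). Abcc4, an exporter on the blood side of the hepatocyte, rose from 2.24 ± 0.239 to 8.42 ± 1.09 CPM (SD, n = 3; adjusted p = 0.00256, edgeR). In the sensing list 9 of 11 genes fell and 1 rose, with the same counts adjusted over the list alone and a median of -1.88 (camera adjusted p = 0.000403, but adjusted p = 0.177 with an estimated correlation). Nr1i3, the receptor CAR, fell from 94.1 ± 11.6 to 25.9 ± 1.20 CPM (SD, n = 3), but 68.1% of its 31-base words occur in another gene, so it is uncertain. Klb, the FGF co-receptor, fell by 2.55 ± 0.32 on the log2 scale (SE). Nr0b2, encoding the repressor SHP, fell by 1.72 ± 0.23 and the FGF receptor gene Fgfr4 fell by 1.93 ± 0.29 (SE). Vdr, the vitamin D receptor gene, rose by 2.16 ± 0.54 (SE; adjusted p = 0.0162), was named after its values were seen, and missed the threshold without Sirt5+/+ replicate 2 or Sirt5-/- replicate 2 or 3 (adjusted p up to 0.0767), and its log2 change was 2.75 without Sirt5+/+ replicate 3. With library totals Abcb11, Abcg5, Nr1i3, Nr0b2 and Fgfr4 missed it as well (log2 changes of -1.75, -1.41, -1.27, -1.04 and -1.39, adjusted p = 0.0653, 0.152, 0.207, 0.333 and 0.161).

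Hepatocyte markers moved with these lists. Of 19 measured markers 14 fell (18 adjusted over the list alone), with a median of -1.86 (camera adjusted p = 2.13e-08, but adjusted p = 0.177 with an estimated correlation). F2, prothrombin, fell from 1274 ± 712 to 179 ± 34.0 CPM (SD, n = 3). Taken relative to the mean hepatocyte marker level of each library, a measure added after seeing the data, the bile acid synthesis list differed by 0.02 between genotypes (exact permutation test, two-sided, p = 0.9, adjusted p = 0.969 over 14 lists). On this measure the transport and sensing lists were 0.63 and 0.51 higher in Sirt5-/-, so they fell less than the markers (exact p = 0.1 each, the smallest that 3 against 3 can give, adjusted p = 0.35). The 14 lists ran from -0.23 (urea cycle and ammonia, exact p = 0.3) to 0.74 (oxidative phosphorylation, exact p = 0.1), with the tricarboxylic acid cycle at 0.69 (exact p = 0.1) and fatty acid oxidation at 0.06 (exact p = 0.7). Single genes were also tested relative to the markers (limma, adjusted p under 0.05). Synthesis had 2 higher and 2 lower, transport 4 and 0, and sensing 2 and 0. Oxidative phosphorylation had 11 and 0, the tricarboxylic acid cycle 8 and 0, the urea cycle list 0 and 1, and mitochondrial fatty acid oxidation 0 and 0.

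Other metabolic lists were lower too, the oxidative phosphorylation and tricarboxylic acid cycle lists with smaller medians. Of 22 genes of mitochondrial fatty acid oxidation and ketogenesis, 21 fell (22 adjusted over the list alone; median -1.89, camera adjusted p = 5.46e-09, but adjusted p = 0.177 with an estimated correlation), among them Decr1 by 2.12 ± 0.29 and the carnitine palmitoyltransferase gene Cpt2 by 1.84 ± 0.26 (log2, SE). Peroxisomal fatty acid oxidation had 13 of 15 genes lower, also adjusted over the list alone (camera adjusted p = 6.39e-07, but adjusted p = 0.177 with an estimated correlation), with Pex11a falling from 42.0 ± 1.73 to 9.09 ± 1.40 CPM (SD, n = 3) and Acot4 by 2.50 ± 0.26 (log2, SE). In the urea cycle and ammonia list 12 of 13 fell (13 adjusted over the list alone; camera adjusted p = 7.28e-07, but adjusted p = 0.177 with an estimated correlation), including the carriers Slc25a15 and Slc25a13 by 2.23 and 1.93. Oxidative phosphorylation had 22 of 28 lower (23 adjusted over the list alone; median -1.24, camera adjusted p = 4.00e-07, but adjusted p = 0.177 with an estimated correlation), such as Uqcrfs1 and Uqcrc2 of complex III at -1.57 and -1.34. The tricarboxylic acid cycle had 14 of 21 lower (17 adjusted over the list alone; median -1.26, camera adjusted p = 3.91e-06, but adjusted p = 0.188 with an estimated correlation), with Suclg2 at -1.59 and Sdha at -2.82. In that list Sirt5+/+ replicate 3, with 46.4% mitochondrial reads, had a mean centred log2 level of 0.08, against 0.93 and 0.79 in the other Sirt5+/+ livers. With library totals the genes named in this paragraph missed the threshold except Sdha (adjusted p from 0.0562 for Acot4 to 0.501 for Uqcrc2).

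Lipid synthesis and drug metabolism followed the same direction. Of 21 cholesterol synthesis genes 16 fell (17 adjusted over the list alone; median -1.61, camera adjusted p = 1.07e-05, but adjusted p = 0.323 with an estimated correlation), with Sc5d and Idi1 at -2.11 and -1.58. The mean centred log2 level of that list was -0.21 in Sirt5+/+ replicate 3, against 1.34 and 1.01 in the other Sirt5+/+ livers and -0.51 to -0.90 in Sirt5-/-. Fatty acid synthesis had 12 of 14 lower, also adjusted over the list alone (camera adjusted p = 4.02e-06, but adjusted p = 0.188 with an estimated correlation), with Elovl5 at -1.65 and Dgat2, a triglyceride synthase, at -2.76. Sirt5+/+ replicate 3 stood apart in this list too, at 0.37 against 1.32 and 1.15, and in the pericentral list, at 0.18 against 1.34 and 1.02. Xenobiotic cytochrome P450 genes had 12 of 13 lower (13 adjusted over the list alone; camera adjusted p = 1.27e-06, but adjusted p = 0.177 with an estimated correlation), with Cyp3a13 at -2.19 and Cyp2a5 at -2.24, which is uncertain, since 54.6% of its 31-base words occur in other genes. Pericentral genes (12 of 16 lower, 13 adjusted over the list alone; camera adjusted p = 2.01e-05, but adjusted p = 0.195 with an estimated correlation) and periportal genes (16 of 19 lower, 17 adjusted over the list alone; camera adjusted p = 7.28e-07, but adjusted p = 0.195 with an estimated correlation) were both lower, with Lhpp and Oat at -1.79 and -2.48 and Etnppl at -3.08. The periportal gene that rose was Ctsc, a lysosomal protease of leukocytes too, at 2.62. Male-biased liver genes had 14 of 20 lower (18 adjusted over the list alone; camera adjusted p = 1.56e-07, but adjusted p = 0.177 with an estimated correlation), with Elovl3 falling from 82.3 ± 43.2 to 6.07 ± 1.03 CPM (SD, n = 3) and Hsd3b5, uncertain with 34.1% of its words in other genes, by 2.33. Circadian clock genes had 8 of 17 lower (9 adjusted over the list alone; median -0.96, camera adjusted p = 0.00480, but adjusted p = 0.177 with an estimated correlation), with Hlf and Tef at -1.99 and -1.67. With library totals Sc5d, Idi1, Elovl5, Cyp3a13, Cyp2a5, Lhpp, Hlf and Tef missed the threshold (adjusted p from 0.0573 for Cyp2a5 to 0.308 for Elovl5).

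Mixed or weaker lists were the following. In the glutathione and NRF2 list 9 of 18 genes fell and 2 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.0286, but adjusted p = 0.294 with an estimated correlation), with Gsta4 at -2.15 and Hmox1 at 1.27. G6pdx, which makes NADPH, rose from 6.17 ± 0.594 to 26.2 ± 4.83 CPM (SD, n = 3). The list's call ended without Sirt5+/+ replicate 1 (adjusted p = 0.0594), with library totals (median -0.51 against -1.08, adjusted p = 0.0651) and with a GC offset (0.0532). That of Hmox1, named after its values were seen, ended without Sirt5-/- replicate 3 (adjusted p = 0.0537). Glycolysis and gluconeogenesis had 10 of 23 genes lower and 7 higher (11 and 7 adjusted over the list alone) and did not pass as a list (camera adjusted p = 0.259, and 0.401 with an estimated correlation). The list passed, as lower, with library totals (adjusted p = 0.0267) and without the richest mitochondrial library of each genotype (0.0347). Its member Slc2a1, the glucose transporter GLUT1, rose by 1.77. Female-biased liver genes had 3 of 6 measured members lower, also adjusted over the list alone, and did not pass (camera adjusted p = 0.0800, and 0.195 with an estimated correlation), and they passed, as lower, in 9 other settings. These were without Sirt5+/+ replicate 1 or any 1 Sirt5-/- library (adjusted p from 0.00822 to 0.0419), library totals (0.00773), no filter (0.00818), without the richest mitochondrial library of each genotype (0.0453), mitochondrial genes removed (0.0144) and fry (0.0113). The 3 were Cyp2a4 at -5.14 (uncertain, as 58.9% of its words occur in other genes), Cyp17a1 at -2.13 and Fmo2 at -1.22; Fmo2, named after its values were seen, and Cyp17a1 missed the threshold without Sirt5-/- replicate 2 or 3, and Fmo2 also without Sirt5+/+ replicate 2 or Sirt5-/- replicate 1 (adjusted p up to 0.139 and 0.0647). With library totals Gsta4, Cyp17a1 and Fmo2 missed it (adjusted p = 0.0942, 0.173 and 0.538).

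YAP target genes were higher in Sirt5-/-. Of 23 measured targets 20 rose (21 rose and 1 fell adjusted over the list alone), with a median of 1.88 (camera adjusted p = 2.11e-08, but adjusted p = 0.177 with an estimated correlation). Ccn2, encoding the matricellular protein CTGF, rose from 34.0 ± 3.16 to 235 ± 46.6 CPM, and Ccn1, encoding CYR61, from 26.7 ± 7.88 to 286 ± 104 CPM (SD, n = 3). The receptor tyrosine kinase gene Axl rose by 2.70 ± 0.27 and Igfbp3 rose by 2.69 ± 0.29 (log2, SE). The YAP5SA construct has no entry of its own in the table, so its level was not analysed here.

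Cell cycle genes and markers of progenitor cells and tumours rose too. Of 30 cell cycle genes 22 rose and 1 fell (23 and 1 adjusted over the list alone; median 1.65, camera adjusted p = 6.72e-07, but adjusted p = 0.211 with an estimated correlation). Top2a, topoisomerase II alpha, rose by 2.34 ± 0.31 (log2, SE), and Ccnb2, Aurkb and Plk1, genes of mitosis, rose by 3.01, 2.67 and 2.02 on the log2 scale. The gene that fell, Ccne1 at -1.30, was named after its values were seen and missed the threshold without any 1 library except Sirt5+/+ replicate 2 (adjusted p from 0.0579 to 0.158) and with library totals (0.724). Of 18 progenitor and tumour markers 9 rose (10 adjusted over the list alone; median 1.76, camera adjusted p = 9.84e-06, but adjusted p = 0.177 with an estimated correlation). Afp, alpha-fetoprotein, rose from 2.62 ± 0.812 to 25.2 ± 7.75 CPM (SD, n = 3), and Krt19 and Krt7, keratins of bile duct cells, rose by 2.71 and 3.62. Gpc3 rose by 2.83 and Igf2 by 4.23 (5.54 without Sirt5+/+ replicate 3), both named after their values were seen, and 63.1% of the 31-base words of Igf2 also occur in other genes.

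Stress lists were split. Apoptosis and p53 targets had 9 of 18 genes higher, also adjusted over the list alone (camera adjusted p = 0.000676, but adjusted p = 0.177 with an estimated correlation), with Cdkn1a, the inhibitor p21, rising from 9.21 ± 2.58 to 62.2 ± 9.64 CPM (SD, n = 3) and the death receptor gene Tnfrsf10b by 2.71. Immediate early and heat shock genes had 9 of 19 higher (10 adjusted over the list alone; camera adjusted p = 0.000116, but adjusted p = 0.323 with an estimated correlation), with Ier3 and Klf6 at 3.32 and 2.72. Mean centred log2 levels of that list were -0.98, -0.89 and -0.51 in Sirt5+/+ and -0.03, 1.10 and 1.32 in Sirt5-/-, so Sirt5-/- replicate 1, with 40.8% mitochondrial reads, lay apart from the other Sirt5-/- livers. Endoplasmic reticulum stress and ATF4 targets had 4 of 18 higher and 2 lower, the same adjusted over the list alone, and did not pass (camera adjusted p = 0.718, and 0.851 with an estimated correlation). The serine synthesis genes Psat1 and Phgdh rose by 2.80 and 2.65, and Phgdh is uncertain, with 56.3% of its 31-base words in other genes. Ddit3 and Sdf2l1 at 1.40 and 1.01, and Herpud1 and Xbp1 at -1.89 and -1.40, were named after their values were seen. Without Sirt5+/+ replicate 1 or 2 or Sirt5-/- replicate 2 or 3, Ddit3, Sdf2l1 and Xbp1 missed the threshold (adjusted p up to 0.109, 0.154 and 0.0844), Xbp1 also without Sirt5-/- replicate 1, and Ddit3 was at 2.04 without Sirt5+/+ replicate 3. With library totals Sdf2l1, Herpud1 and Xbp1 missed it (log2 changes of 1.83, -1.31 and -0.84, adjusted p = 0.0518, 0.191 and 0.445), Sdf2l1 with a larger change than in the main fit.

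**Figure D2:**
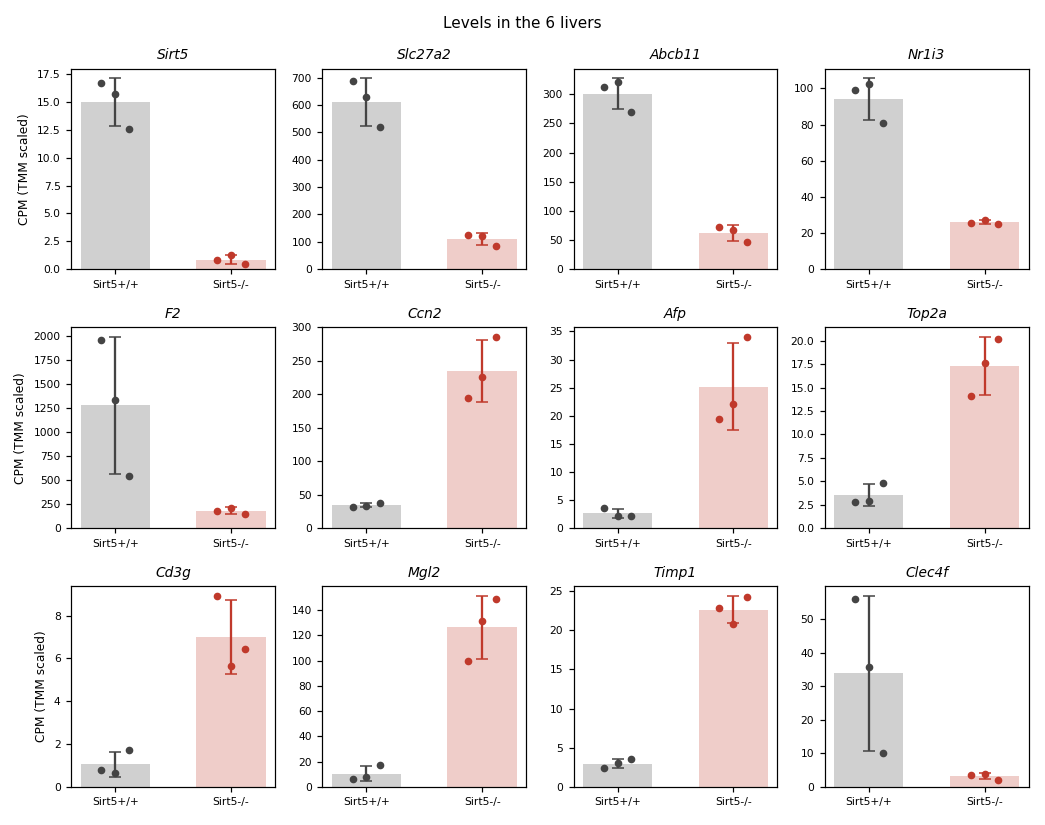
Levels of 12 genes in the 6 livers, in CPM after TMM scaling (y axis, starting at 0). Points are single livers, bars the mean of 3 and error bars the SD; genotypes do not overlap in any panel, Clec4f was named after its values were seen, and Ccn2 runs from 34.0 to 235 CPM while Abcb11 runs from 301 to 61.5 CPM on average.

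Immune cell genes were higher, with exceptions among genes of resident macrophages. Of 20 macrophage markers 12 rose and 3 fell (12 and 4 adjusted over the list alone), with a median of 2.13 (camera adjusted p = 0.00642, but adjusted p = 0.265 with an estimated correlation). Aif1 rose from 3.70 ± 0.802 to 59.0 ± 12.3 CPM and C1qc, a complement component, from 60.9 ± 9.64 to 573 ± 186 CPM (SD, n = 3). The Fc receptor gene Fcgr1 and the endotoxin co-receptor gene Cd14 rose by 3.03 and 3.37. Clec4f, Cd5l and Marco, known from resident Kupffer cells, fell by 3.42 ± 0.59, 3.26 ± 0.62 and 2.57 ± 0.43 (log2, SE), and were named after their values were seen. The list lost its call without Sirt5+/+ replicate 3 (adjusted p = 0.117) and without the richest mitochondrial library of each genotype (adjusted p = 0.0709), and Marco lost its call with library totals (adjusted p = 0.0836). Without Sirt5+/+ replicate 1 the log2 change of Clec4f was -2.82.

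M1-type and M2-type macrophage lists were both higher in the members that could be tested. Nos2, Il6, Il12a, Il12b and Il23a of the M1-type list were too low to be tested (at most 30, 10, 11, 7 and 9 counts in a library). So were Chil3, Il10 and Pdcd1lg2 of the M2-type list (at most 21, 3 and 4 counts). The M1-type list had 9 of 13 genes higher (10 adjusted over the list alone; median 2.29, camera adjusted p = 1.58e-05, but adjusted p = 0.177 with an estimated correlation), with Il1b rising from 0.944 ± 0.296 to 24.1 ± 16.7 CPM (SD, n = 3), and Ccl5, Cxcl10 and Cxcl9 by 2.83, 2.70 and 2.29. In the M2-type list 8 of 17 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.56, camera adjusted p = 0.000622, but adjusted p = 0.177 with an estimated correlation), with the lectin gene Mgl2 rising from 10.5 ± 6.12 to 126 ± 24.8 CPM (SD, n = 3), a log2 change of 3.61 that was 4.22 without Sirt5+/+ replicate 3. Clec7a, Msr1 and Tgfb1 rose by 2.82, 2.54 and 1.88. The gene that fell was Arg1 at -1.71, which is also a urea cycle enzyme of hepatocytes, named after its values were seen, and it missed the threshold without Sirt5-/- replicate 2 or 3 (adjusted p = 0.114 and 0.0903) and with library totals (0.259).

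T and NK cell markers had 11 of 16 measured genes higher and 1 lower (15 and 1 adjusted over the list alone; median 2.21, camera adjusted p = 6.38e-06, but adjusted p = 0.177 with an estimated correlation). The list members Cd28, Ncr1, Gzma, Prf1, Ifng, Eomes and Tbx21 were too low to be tested, with highest counts in a library from 6 to 20. Cd3g and Cd3d, parts of the T cell receptor complex, rose by 2.84 ± 0.45 and 2.29 ± 0.42 and Cd2 by 2.25 ± 0.38 (log2, SE). Trac, the constant part of the receptor's alpha chain, rose from 0.789 ± 0.0312 to 3.41 ± 0.656 CPM (SD, n = 3). Zap70 fell by 2.04, was named after its values were seen, and missed the threshold without any 1 library except Sirt5+/+ replicate 3 (adjusted p from 0.0769 to 0.155) and with library totals (0.196), and its log2 change was -1.40 without Sirt5+/+ replicate 1. Of 12 regulatory T cell and checkpoint genes 6 rose (9 adjusted over the list alone; median 1.95, camera adjusted p = 5.86e-05, but adjusted p = 0.177 with an estimated correlation). Havcr2, encoding TIM-3, and Lag3 rose by 3.03 and 2.08 (Havcr2 by 3.69 without Sirt5+/+ replicate 2), and Tigit had 2 counts over the Sirt5+/+ libraries and 74 over the Sirt5-/- libraries (ratio 23.4, 95% counting interval 6.26 to 197). Ikzf4 rose by 1.89 and missed the threshold without Sirt5-/- replicate 1 or 3 (adjusted p = 0.0604 and 0.0766).

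Chemokine and antigen presentation genes were also higher. Of 19 chemokine and cytokine genes 8 rose and 1 fell (11 and 2 adjusted over the list alone; median 1.47, camera adjusted p = 0.000820, but adjusted p = 0.177 with an estimated correlation). Csf1, the macrophage growth factor, rose from 54.5 ± 31.2 to 541 ± 61.2 CPM (SD, n = 3), a log2 change of 3.32 that was 3.95 without Sirt5+/+ replicate 3. Cxcl16 and Ccl6 rose by 2.93 and 1.98, while Cxcl12, named after its values were seen, fell by 1.54. Dendritic cell and antigen presentation markers had 12 of 17 higher, also adjusted over the list alone (median 2.25, camera adjusted p = 1.90e-06, but adjusted p = 0.188 with an estimated correlation), with Batf3 at 3.40 and H2-DMb1, uncertain with 31.4% of its 31-base words in another gene, at 2.96. B and plasma cell markers had 7 of 15 higher, also adjusted over the list alone (camera adjusted p = 0.000138, but adjusted p = 0.177 with an estimated correlation), with Ighm at 2.30 and Cd22 at 2.09. The interferon response had 15 of 27 higher (16 adjusted over the list alone; camera adjusted p = 2.06e-05, but adjusted p = 0.177 with an estimated correlation), with Oasl2 and Isg15 at 2.09 and 1.71. Of 5 measured neutrophil markers 3 rose, also adjusted over the list alone (camera adjusted p = 0.0382, but adjusted p = 0.177 with an estimated correlation), namely Lcn2, Csf3r and Prtn3 at 2.25, 2.01 and 2.37. That call ended without any 1 of the 6 libraries (adjusted p from 0.111 to 0.312), where the list median was 0.34 to 1.02, against 2.01 with all libraries. The filter was applied anew in these fits and more genes were tested (15123 to 15608, against 14799), so the low-count members measured may differ. The neutrophil call also ended without the richest mitochondrial library of each genotype (0.0920), with upper-quartile factors (0.0521) and with no filter (median 0.08, adjusted p = 0.207). Prtn3, named after its values were seen, missed the threshold without Sirt5-/- replicate 2 or 3 (adjusted p = 0.0580 and 0.0594). Acute phase genes had 8 of 20 lower and 3 higher (10 and 3 adjusted over the list alone; camera adjusted p = 0.0461, but adjusted p = 0.435 with an estimated correlation), with Crp at -2.30 and Lcn2, Orm2 and Saa3 at 2.25, 1.37 and 1.34. Orm2 is uncertain, with 34.1% of its words in other genes. The mean centred log2 level of the acute phase list was -0.02 in Sirt5+/+ replicate 3, against 0.73 and 0.40 in the other Sirt5+/+ livers. With library totals Cxcl12 and Crp missed the threshold (adjusted p = 0.333 and 0.0574). The acute phase call ended without Sirt5+/+ replicate 1 (adjusted p = 0.0621) or Sirt5-/- replicate 3 (0.110), with a stricter filter (0.0828), the mitochondrial share as a covariate (0.0540), a GC offset (0.0754) and fry (0.118). That of Saa3, named like Orm2 after its values were seen, ended without Sirt5+/+ replicate 2 or Sirt5-/- replicate 1 or 2 (adjusted p up to 0.0777).

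Lists of stellate cell and bile duct cell genes were higher. Stellate cell and fibrosis genes had 15 of 24 higher and 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 1.36e-05, but adjusted p = 0.177 with an estimated correlation), with Timp1, a protease inhibitor of scar tissue, rising from 2.97 ± 0.583 to 22.6 ± 1.76 CPM (SD, n = 3) and Thy1 by 2.88, while Reln, named after its values were seen, fell by 1.48. Of 18 cholangiocyte markers 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0109, but adjusted p = 0.195 with an estimated correlation). Among those that rose were Krt19, Ezr, Krt7 and Bicc1 at 2.71, 2.87, 3.62 and 1.94, and Onecut1 fell by 1.99. Bicc1 and Onecut1 were named after their values were seen, and Onecut1 missed the threshold without Sirt5+/+ replicate 2 or Sirt5-/- replicate 2 or 3 (adjusted p from 0.120 to 0.131) and was at -2.79 without Sirt5-/- replicate 1. With library totals Reln and Onecut1 missed it (adjusted p = 0.481 and 0.117), and Onecut1 is uncertain, with 53% of its 31-base words in other genes.

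Endothelial markers did not pass as a list (6 of 18 fell and 2 rose, 6 and 3 adjusted over the list alone; camera adjusted p = 0.228, and 0.628 with an estimated correlation). The median of -0.08 became 0.53 with library totals and 0.10 with upper-quartile factors. Gpr182 and Oit3, known from liver sinusoids, fell by 2.60 and 3.33 on the log2 scale. Cd34, a marker of capillary endothelium, and Flt1 rose by 1.66 and 0.89, were named after their values were seen, and Flt1 missed the threshold without Sirt5+/+ replicate 1 or any 1 Sirt5-/- library (adjusted p from 0.0827 to 0.157). Of 8 erythroid markers 2 fell, also adjusted over the list alone (camera adjusted p = 0.0319, but adjusted p = 0.323 with an estimated correlation), Alas2 by 2.41 and Klf1 by 1.55, and its mean centred log2 level was 0.00 in Sirt5-/- replicate 1 against -0.55 and -0.63 in the other Sirt5-/- livers. The list lost its call without Sirt5-/- replicate 2 or 3 (adjusted p = 0.0583 and 0.0577), with a stricter filter (0.0529) and with library totals (median -0.07, adjusted p = 0.0616), and Klf1 lost its call without those or Sirt5+/+ replicate 1 or 2 (adjusted p from 0.0526 to 0.101). Of 5 measured pancreas and gut markers 2 fell, also adjusted over the list alone (camera adjusted p = 0.0344, but adjusted p = 0.177 with an estimated correlation), Fabp2 and Cela1 at -1.52 and -2.29. The call ended with no filter (adjusted p = 0.0956) and with the mitochondrial share as a covariate (0.0942). With library totals Flt1, Klf1, Fabp2 and Cela1 missed the threshold (log2 changes of 1.43, -1.06, -0.97 and -1.82, adjusted p = 0.159, 0.395, 0.368 and 0.0682), Flt1 with a larger change than in the main fit. Adipose and mesothelial markers had 2 of 5 higher, also adjusted over the list alone, and did not pass (camera adjusted p = 0.0913, and 0.294 with an estimated correlation; fry adjusted p = 0.00265, higher). Msln, mesothelin, rose from 15.1 ± 5.80 to 237 ± 19.5 CPM (SD, n = 3), and Lep, with no count in Sirt5+/+, was at least 9.91-fold higher against a floor of 3 counts over the group (list median 0.46 with or without this bound, and 1.16 without Sirt5+/+ replicate 3).

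The largest rises and falls named by the fixed rule mixed immune, liver and little-studied genes, with genotypes apart in all 6 livers. Ccl8 and Ccl12, neighbouring monocyte chemokine genes on chromosome 11 (82115185 to 82116799 and 82101845 to 82103400, GRCm38), rose by 5.32 ± 0.66 and 5.09 ± 0.50 (log2, SE; adjusted p = 0.00185 and 0.00146, edgeR). Vxn had 0 counts in Sirt5+/+ and 199 in Sirt5-/-, at least 42-fold higher against a floor of 3 counts over the group. Ratios for genes with 1 to 3 counts over the Sirt5+/+ libraries, with 95% counting intervals, were 152 (27.1 to 6050) for the hyaluronan synthase gene Has2 and 126 (22.3 to 5000) for the transcription factor gene Lhx9. They were 67.7 (18.5 to 563) for Ccdc106, 44.9 (15.2 to 220) for Tmem171 and 39.4 (13.3 to 193) for Nrip3. Cd300ld3, with a ratio of 1060 (293 to 8760), shares 84.1% of its 31-base words with Cd300ld5, and Ccdc106 shares 60% with other genes, so both are uncertain. The fitted fold change, not its log2 value, moved by a factor above 1.5 without 1 library in several of these genes. Without Sirt5+/+ replicate 1 those of Has2, Nrip3, Tmem171 and Cd300ld3 were 9.02, 8.75, 6.12 and 12.62, against 6.82, 5.18, 5.26 and 9.59 with all libraries. Without Sirt5+/+ replicate 2 those of Lhx9 and Ccdc106 were 8.69 and 8.70 against 6.62 and 5.83, and those of Has2, Nrip3 and Cd300ld3 were 6.02, 4.35 and 8.72. Without Sirt5+/+ replicate 3 Ccl8 was at 6.39, and without Sirt5-/- replicate 3 Cd300ld3 was at 8.92.

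Camk2b, a calcium/calmodulin-dependent kinase gene (chromosome 11, 5969644 to 6066362, minus strand), fell from 511 ± 277 to 1.38 ± 0.219 CPM (SD, n = 3), a log2 change of -8.54 ± 0.56 (SE; adjusted p = 0.00145, edgeR). Its counts were 6983, 10422 and 6333 in Sirt5+/+ and 28, 46 and 45 in Sirt5-/-. Nlrp12, a regulator of inflammation, fell by 6.61 ± 0.72 (SE), from 18.3 ± 5.08 to 0.167 ± 0.214 CPM (SD, n = 3), and was at -8.70 without Sirt5-/- replicate 2. Slc10a5, Lrtm1 and Cyp2c29 fell by 4.58, 4.36 and 4.29, but Slc10a5 by 3.64 without Sirt5+/+ replicate 2 and Cyp2c29 by 3.70 without Sirt5+/+ replicate 1. Cyp2a4, Ces2c, Afmid, Tymp and Serpina3m had log2 changes of -5.14, -4.87, -4.50, -4.22 and -4.49 and are uncertain, since 58.9, 50.1, 44.9, 41.2 and 35% of their 31-base words occur in other genes. Without Sirt5+/+ replicate 1 Afmid, Tymp and Serpina3m were at -3.82, -3.46 and -3.86. Sirt5+/+ replicate 3 had the lowest level of that genotype in all 5, such as 3.28 CPM of Tymp and 7.73 CPM of Serpina3m, against at most 2.95 and 5.77 CPM in Sirt5-/-.

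Annotation terms carried by the deposited table were tested as well. Of 3425 terms 695 were enriched, 435 among higher and 260 among lower genes (one-sided Fisher's exact test, Benjamini-Hochberg adjusted). Lower genes held 219 of 432 with oxidoreductase activity (77.1 expected, adjusted p = 9.59e-53), 67 of 102 of the peroxisome (18.2 expected, adjusted p = 1.52e-23) and 29 of 62 of bile secretion (12.8 expected, adjusted p = 0.000107). Higher genes held 93 of 212 of the inflammatory response (37.9 expected, adjusted p = 3.79e-16), 77 of 182 of the extracellular matrix (32.5 expected, adjusted p = 1.87e-12) and 45 of 128 of Hippo signalling, the pathway that restrains YAP (24.7 expected, adjusted p = 0.000402). Some terms passed where the list nearest in subject did not. The glycolysis and gluconeogenesis term held 27 of 78 among lower genes (16.1 expected, adjusted p = 0.0303), and angiogenesis held 65 of 180 among higher genes (32.1 expected, adjusted p = 2.80e-07). The 8 terms given here were picked by subject after their values were seen.

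Lists that track technical differences did not pass. Of 12 measured neighbours of Sirt5 on chromosome 13, 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.704, and 0.711 with an estimated correlation). Their median of -0.31 became 0.28 with library totals. Cd83 and Edn1 rose by 3.01 and 2.05, and Mcur1 and Dtnbp1, named after their values were seen, fell by 0.93 and 0.97. Without Sirt5-/- replicate 2 or 3, Edn1, Mcur1 and Dtnbp1 missed the threshold (adjusted p up to 0.0528, 0.103 and 0.0955), Dtnbp1 also without Sirt5-/- replicate 1, and with library totals Mcur1 and Dtnbp1 did (0.770 and 0.742). None of 12 mitochondrially encoded genes passed in edgeR, over all genes or adjusted over the list alone, and their median of -0.90 differed in sign from the list test (camera adjusted p = 0.825, direction higher, and 0.949 with an estimated correlation). The smallest p among them was that of mt-Nd4l (log2 change -2.37, adjusted p = 0.225, edgeR), which turned to 1.76 without Sirt5+/+ replicate 3 (adjusted p = 0.0207) and was -2.95 without Sirt5+/+ replicate 2. That median became 0.40 with library totals, and 2.20 without Sirt5+/+ replicate 3, where the list passed (adjusted p = 0.00933), and -1.78 without Sirt5-/- replicate 1. Without the richest mitochondrial library of each genotype it passed too, with a median of 1.26 (adjusted p = 0.00432). Values of these genes are uncertain, as reads are shared with nuclear copies.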

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

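The settings with mitochondrial reads, GC content or sample weights, and the block for terms, were chosen after seeing the data. Of 3500 values of the 176 named genes besides Sirt5 over 20 settings, 3329 kept their direction and side of the threshold, 166 kept the direction but lost the call and 5 reversed. Most of these genes were picked for small p or large changes in these libraries, so this count does not extend to all called genes. Of the 5100 genes called with the main settings, 5022 were also called in the same direction with DESeq2 and 2445 with library totals. Of 809 values of the 45 lists over 18 settings, 731 kept their side of the threshold, 63 lost the call and 15 gained one. Direction was compared only for the 37 lists called with the main settings, of which 0 values reversed. Medians of lists not called did change sign, in 6 settings for endoplasmic reticulum stress, 4 for mitochondrially encoded and 3 for endothelial genes. They also did so in 2 settings for adipose and mesothelial markers and in 1 each for sirtuins and Sirt5 neighbours. The Sirt5 level differed by -3.56 to -4.54 on the log2 scale over the settings. With library totals 2763 genes differed, of which 325 were lower, the share of higher genes was 88.2% against 50.5%, and the median log2 change moved from -0.08 to 0.60, which follows from leaving out the composition factor. The labels number the livers 1 to 3 in each genotype, but same-numbered livers did not deviate together (correlations -0.19, 0.115 and -0.204), and with a replicate block 3643 genes differed, 1978 higher and 1665 lower, 37 lists and 616 terms. Leaving out 1 library at a time, the number of changed genes ran from 2531 (without Sirt5-/- replicate 3) to 7647 (without Sirt5+/+ replicate 3), higher genes from 1441 to 3991 and lower genes from 1090 to 3656, lists from 35 to 37 and the number of enriched annotation terms from 502 to 677. Without the library richest in mitochondrial reads of each genotype 7439 genes differed, 3904 of them higher, and with limma-voom sample weights 8247 did, 3989 higher and 4258 lower; the cause was not tested. Other tools and filters gave 4476 to 5787 genes, with DESeq2 at 5767, limma-voom at 5619, upper-quartile factors at 4916 and a GC offset at 5787, and the mitochondrial share as a covariate gave 6443. With an estimated correlation camera called 0 lists (11 at an unadjusted p under 0.05; fry called 39), and with the mitochondrial covariate and with the GC offset 35 each. The value of mt-Nd4l, not past the threshold at -2.37, was 0.53 with the replicate block, 1.72 without the 2 libraries rich in mitochondrial reads and 1.82 with sample weights, and from -2.95 to 1.76 leaving out 1 library at a time; the 1 library that set its sign was Sirt5+/+ replicate 3, which held 21905 of its counts. Yap1 moved from -0.37 to 0.28 with library totals. GC content correlated with log2 fold change at -0.032 (Spearman) over all tested genes, but at -0.567, -0.408 and -0.127 between pairs of Sirt5+/+ libraries. Alternatives for the pseudocount and for a filter on low values were not run, as they applied only to tables without counts. In the simulated data few 2-fold changes were recovered, so the genes not called could include changes of that size. That recovery need not carry over, as the simulation changed only a small share of genes while 34.5% of tested genes were called here.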

Other observations

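The tests of libraries rich in mitochondrial reads, of equal rise of all other cells, of plasmid uptake, of the chromosome segment around Sirt5, and of reads shared by Camk2b and by Gm4737 were chosen after the result was seen.

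Genes of recruited monocytes not in the first lists were higher in Sirt5-/-, with 9 of 12 rising (mean log2 change 1.79 ± 0.28, SEM over genes; camera adjusted p = 0.000217, but adjusted p = 0.182 with an estimated correlation), among them Ms4a6c at 3.13 (uncertain, with 58.1% of its 31-base words in other genes), Ms4a4c at 3.23 and the fractalkine receptor gene Cx3cr1 at 2.84. Other resident Kupffer cell genes did not pass as a list (mean -0.45 ± 0.47, SEM; camera adjusted p = 0.662, and 0.846 with an estimated correlation), with Fcna, Nr1h3 and Slc40a1 falling by 3.06, 2.06 and 1.79 and Sdc3 and Id3 rising by 1.35 and 1.05. Of 11 other sinusoidal endothelial genes 6 fell and 1, Fcgr2b at 1.55, rose (camera adjusted p = 0.00850, but adjusted p = 0.182 with an estimated correlation), among them Wnt2 at -2.78, Aass at -1.51 and Flt4 at -1.24. Of 11 other capillary and vessel genes 4 rose (camera adjusted p = 0.0188, but adjusted p = 0.182 with an estimated correlation), namely Cav1, Ly6a, Esm1 and Vwa1 at 3.05, 1.75, 1.70 and 1.49, of which Ly6a is uncertain, with 31.9% of its words in other genes. Nr1h3, Slc40a1 and Aass are also expressed in hepatocytes, whose markers had a median of -1.86. The genes in this paragraph were named after their values were seen. Id3, Aass, Esm1 and Vwa1 missed the threshold without Sirt5-/- replicate 2 or 3 (adjusted p up to 0.0604, 0.0835, 0.0920 and 0.129), Vwa1 also without Sirt5+/+ replicate 1 or 2, and Wnt2 without Sirt5-/- replicate 2 (adjusted p = 0.0501). Without Sirt5+/+ replicate 1 Fcna was at -2.35, and without Sirt5+/+ replicate 3 Ms4a4c and Cav1 were at 4.02 and 3.91. With library totals Nr1h3, Slc40a1, Id3, Wnt2, Aass and Flt4 missed it (log2 changes of -1.58, -1.26, 1.74, -2.31, -0.90 and -0.65, adjusted p from 0.0556 for Wnt2 to 0.581 for Flt4).

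Hepatocyte genes were lower in Sirt5-/-, while YAP target, immune, cell cycle and matrix genes were higher. Of 416 called members of called lists, 413 (99.3%) kept call and direction in edgeR without the 2 libraries rich in mitochondrial reads. These libraries were thus not needed for the pattern, but a wider influence of mitochondrial reads stays open. The members were picked as called with all 6 libraries, and the 2 libraries lay nearest the other genotype in 28 and 25 of 37 lists. Mitochondrial shares also still differed between the other libraries (7.20 and 6.58% against 21.5 and 17.5%). A lower share of hepatocytes with every other cell type rising alike is argued against by T and NK cell and endothelial markers. The first mean log2 change exceeded the second by 2.51 ± 0.44 (SE over genes, without the spread between livers). They were picked as highest and lowest of the macrophage, T and NK cell, endothelial, stellate and cholangiocyte lists. Mean centred log2 levels of T and NK cell markers were -0.88, -1.09 and -0.93 in Sirt5+/+ and 0.98, 0.92 and 1.00 in Sirt5-/-. Those of endothelial markers were 0.25, 0.61 and -0.19 against -0.06, -0.23 and -0.38. A lower share of hepatocytes together with changes in the other cells stays open. Unequal plasmid uptake cannot be told apart from an effect of Sirt5 loss, as the construct has no entry in the table and mouse Yap1 differed by -0.37 (adjusted p = 0.201, edgeR). An effect of Sirt5 loss on these livers stays open as an untested hypothesis.

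Within myeloid and endothelial cells, marker genes of subsets differed in their mean log2 change. The added lists hold genes not used to find this difference, but measured in the same livers, so they are not an independent test. In them, recruited monocyte genes exceeded resident Kupffer cell genes by 2.23 ± 0.55 (SE over genes), although the resident list did not pass by itself. Capillary genes exceeded sinusoidal endothelial genes by 1.88 ± 0.43 (SE over genes). These SE leave out the spread between livers, and none of these lists passed with an estimated correlation (camera, adjusted p from 0.182 to 0.846). Bulk RNA does not separate a change in cell numbers from a change within cells, and no technical explanation was tested for this pattern.

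Some genes were near on or off between the genotypes, which could come from strain differences or from shared reads. Of 127 genes called with a fold of at least 16, 2.36% lay within 20 Mb of Sirt5, against 1.59% of tested genes (two-sided Fisher's exact test, p = 0.459), which argues against a strain segment around the targeted locus as the source of most of them. For Camk2b 0.371% of 31-base words occur in other genes, which argues against shared reads, and a variant elsewhere in the genome stays open. Gm4737 (log2 change -12.50, and -17.04 and -11.88 without Sirt5-/- replicate 2 or 3) has 93.2% of its words in Ahcy and took 51.4, 50.4 and 19.9% of their summed level in Sirt5+/+ but 0, 0.0857 and 0% in Sirt5-/-, so its change may reflect how shared reads were divided. Ahcy itself fell by 1.31 and the sum by 2.14, and Ahcy missed the threshold without Sirt5+/+ replicate 1 or 2 or Sirt5-/- replicate 2 or 3 (adjusted p from 0.0509 to 0.155) and with library totals (0.526).

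The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For the number of changed genes 1 of 10 splits, the real one, gave as many, 5100 against at most 0 in the others (edgeR; up to 906 at an unadjusted p under 0.05, up to 56 with DESeq2 and 0 with limma-voom). For lists 1 of 10 gave as many, 37 against at most 33, and for terms 1 of 10, 695 against at most 0 (Fisher's exact test on the genes called by edgeR). With 0 genes called in the mixed splits no term could be enriched there, so the count of terms adds nothing to that of genes. The split that gave 33 lists set Sirt5+/+ replicates 1 and 2 with Sirt5-/- replicate 1 against the rest, and each mixed split still set 2 libraries of a genotype against 1.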
